A study of Mus musculus with 2 samples.

How the data were processed

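Spleen tissue of adult C57BL/6J mice at 8 weeks of age was profiled by RNA sequencing. Per the labels, the libraries were made from RNA longer than 200 nucleotides that had been depleted of ribosomal RNA and selected for a poly(A) tail, kept the strand of the transcript, held added spike-in RNA, and were read from both ends with reads of 76 nucleotides. The 2 samples are biological replicates 1 and 2 of a single group and are called library 1 and library 2. The labels give no second group, so no conditions were compared.

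The gene and transcript tables hold 1 library each and use the mm10 assembly with annotation version M4 of GENCODE, per the deposited notes that accompany the files. The same notes state that the values were computed from alignments to the transcriptome, each from 1 biological replicate. The aligner, the quantification tool, their versions and the strand setting are not given in the sources used here. The deposited expected counts are estimated numbers of reads per gene or transcript, need not be whole, and were not normalized. The deposited TPM values, transcript abundances brought to a fixed total, and the posterior mean TPM values are scaled over all entries of a table, spike-ins included. The deposited FPKM values are fragment numbers divided by transcript length and by the fragments of the library. The deposited transcript tables also give the percent of its gene's TPM that each transcript holds. Reads that match several genes were divided among them by the authors' estimation, so the values of near-identical paralogs, pseudogenes and overlapping genes are uncertain. A list of contigs, which are stretches of continuous coverage, and a list of splice junctions cover the whole series on the older mm9 assembly, per the deposited notes. These deposited lists have no column names. Their columns were taken, from their values and the format named in the deposited notes, as the count of reads at each junction, the coverage level or signal of each contig, and an irreproducibility value for each entry, read here like a p-value. How the lists were made is not given in the sources used here.

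The gene tables list 43346 genes, 97 spike-ins and 26248 further entries that held 0 counts in both libraries. Spike-ins and those further entries were left out of library sizes and tests. Gene symbols and positions were taken by unversioned identifier from GENCODE version M21 of the same GRCm38 assembly, which matched 42462 identifiers (98.0%). Identifiers without a symbol held 0.132% of gene counts in library 1 and 0.128% in library 2. No mm9 annotation was used, so contigs and junctions are given by position alone.

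Levels are TPM, as the mean ± SD of the 2 libraries. Ratios between libraries are of expected counts divided by library sizes scaled with TMM, a trimmed mean of log ratios. Scaling was done in edgeR 4.0.16 under R 4.3.3. Log2 ratios, and the 2-fold limits set on them, use a prior count of 2. Folds and counting intervals of single genes use no prior count, so at low counts they can differ from the log2 ratio. The TMM factors were 1.01 for library 1 and 0.988 for library 2. A gene was counted as detected at 1 TPM or more. The correlation across genes used log2(TPM + 1) over genes at 1 TPM or more in either library. The biological coefficient of variation, the relative spread between replicates beyond counting error, is the square root of edgeR's common dispersion over genes with 10 or more rounded expected counts in each library, and DESeq2 1.42.0 gave an alternative. An exact two-sided binomial test of the rounded expected counts of each gene with 10 or more counts in total, with Benjamini-Hochberg adjustment and a threshold of 0.05, asked whether the libraries differed beyond counting error. That test compares these libraries and says nothing of a condition. With 1 library on each side no replicate check exists for a ratio, and 2 samples allow no exact test over samples that reaches 0.05. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 was read as up to 3 counts. A fold given as at least a value is the ratio to that floor and is not the limit of the exact counting interval, which starts lower, at 257-fold for Dct. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 did the remaining computations.

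The gene lists for 21 resident cell types, 6 programmes, 9 other tissues and 2 library checks, the alternatives, and the rule for naming genes were fixed before the data were examined. A list's level is the median TPM of its measured members. A list's shift is the median log2 ratio of its members with a count, placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list outside percentiles 2.5 to 97.5 was called shifted. The percentile describes these libraries and is not a p-value. The rule named the 20 nuclear protein-coding genes of highest mean TPM, the 4 members of highest mean TPM in each list, any further list member that differed by more than 2-fold and had 50 or more counts in a library, the genes of 10 fixed ratios, the 10 largest ratios in each direction among genes with 100 or more counts in a library, and Ptprc, Ighm, Ighd, Cd44, Ikzf1, Pkm and Cd74 for their transcripts. The values of some genes that the rule names are not reported here. Klf1, Gata1, Xist, Prss3, Gm42418 and the melanocyte, eosinophil and chymotrypsin genes named in the closing part lie outside this rule and were chosen after their values were seen. For that part a second acinar set of 18 genes and lists of 12 melanocyte and 10 eosinophil genes were also written after values had been seen. Tsix, 3 long nuclear transcripts and lists of 8 further melanocyte, 9 epidermal and 5 eye genes were chosen after the data had first been seen but before their own values were. Transcripts were compared in genes with 10 TPM or more in each library and at least 2 annotated transcripts, and a second transcript was called in use at 20% or more of its gene's TPM in both libraries. A junction was counted as covered when the bases on both of its sides lay in contigs of the same strand.

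The alternatives were other scalings (total counts, DESeq2 size factors), other filters and pseudocounts, FPKM and posterior mean TPM, other gene sets, a stricter irreproducibility limit of 0.01 for contigs and junctions, and each library alone. After the data were seen, 5 further alternatives were added: levels without acinar genes, the correlation without acinar genes, shifts without acinar and haemoglobin genes, a fold minimum of 2 beside the binomial test, and shifts after removing the trend of log ratios with GC content and transcript length. The steps were tested on simulated data. Negative binomial counts with coefficients of variation of 0.1, 0.2 and 0.4 gave estimates of 0.0996, 0.199 and 0.393. The binomial test between the libraries was run on Poisson counts of 17328 genes. The changed genes were taken only from genes with counts well above the minimum that this test requires. Of these, 100 of 100 genes changed by 2-fold and 78 of 100 genes changed by 1.25-fold were recovered, and 9 of the unchanged genes were called. Recovery of changed genes near that minimum was not simulated and may be lower. The list shift was tested on random lists of 10 genes, drawn from the upper expression bins of the measured ratios of 21339 genes. Of these lists, 9 of 200 without a change and 200 of 200 raised by 1.41-fold fell outside the percentiles. Unchanged lists came from the same ratios as the lists they were placed among, so their rate was largely set in advance. Lists of other sizes, of genes at low counts or of genes that vary together were not simulated.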

Results

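Poly(A) RNA from the spleen of adult C57BL/6J mice, the common inbred black laboratory strain, was sequenced in 2 biological replicates taken at 8 weeks of age. The samples form a single group. The series therefore addresses which transcripts the adult spleen holds, at what level, and how far libraries of the same tissue differ. The labels describe tissue from littermates of both sexes and leave the sex of each sample unrecorded. They do not say which animals went into which library, so SDs measure only the spread between these 2 samples, which may be technical. The p-values measure departure from counting error between these samples and hold no estimate of that spread. Expected counts assigned to genes came to 49686344 in library 1 and 51393345 in library 2. At this depth a count of 0 allows up to 3 counts, which is 0.0308 TPM in library 1 and 0.0277 TPM in library 2 for a typical gene. Every mean ± SD below is over the 2 libraries (n = 2).

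Transcripts of red blood cells and of the exocrine pancreas led the nuclear protein-coding genes of the spleen RNA. Among these genes, haemoglobin genes, which encode the oxygen carrier of red cells, held 4 of the 20 highest places. Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298 of GRCm38, plus strand) stood at 95798 ± 27036 TPM, Hbb-bs at 80876 ± 27980.3 TPM, Hba-a1 at 59714 ± 17089.8 TPM and Hbb-bt at 12234 ± 5427 TPM. These 4 genes took 19.4% of all TPM in library 1 and 30.3% in library 2. Because Hba-a1 and Hba-a2 are near-identical copies, the division of reads between them is uncertain. Secretory enzymes of the exocrine pancreas held 10 of the same 20 places, led by the chymotrypsinogen Ctrb1 at 29019 ± 11257 TPM, the elastase Cela2a at 17261 ± 397 TPM and the colipase Clps at 9114 ± 563 TPM. The other 6 places were held by the ribosomal protein genes Rplp1 (10899 ± 1618 TPM) and Rps12 (5905 ± 369.8 TPM), the actin gene Actb (7360.5 ± 1999.5 TPM), the antigen presentation genes Cd74 (6916 ± 1099.9 TPM) and H2-Ab1 (4954 ± 1326 TPM), and Igfbp7 (4279 ± 2494 TPM), which encodes a secreted protein of vessel walls. That ranking leaves out other gene types. Of these, Gm42418 (22426 ± 5602 TPM, chosen after its value was seen) and the immunoglobulin genes Igkc and Ighm would also have held a place. Gm42418 is annotated as a lincRNA, and whether its reads come from such a transcript was not tested. Ribosomal protein genes together took 7.45% ± 0.418 of TPM and immunoglobulin constant region genes 2.05% ± 0.451.

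The same genes were detected at similar levels in both libraries. In all, 12500 genes reached 1 TPM in both, of which 11572 were protein-coding, while 13221 reached it in at least 1. Across those 13221 genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.977 and Spearman's rho 0.974. Of the genes detected in both, 98.1% differed by no more than 2-fold, with 126 higher in library 2 and 113 higher in library 1 by more than that. The median absolute log2 ratio was 0.20. The biological coefficient of variation was 0.186 over 15860 genes by edgeR's common dispersion, and 0.0832 by the median of DESeq2's gene-wise dispersions. The deposited libraries hold distinct data, since the chi-square statistic of their counts was 138.7 times its 16382 degrees of freedom. By the exact binomial test, 8824 of 17547 genes differed beyond counting error, 4258 of them higher in library 2 and 4566 higher in library 1, and 977 of the 8824 also differed by more than 2-fold, 614 of them higher in library 2 and 363 higher in library 1. TPM of the median detected gene was 0.903-fold in library 2, beside the larger haemoglobin share there, whereas its TMM-scaled log2 ratio was -0.012. Levels are therefore given as TPM and differences as TMM-scaled ratios.

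**Figure D1:**
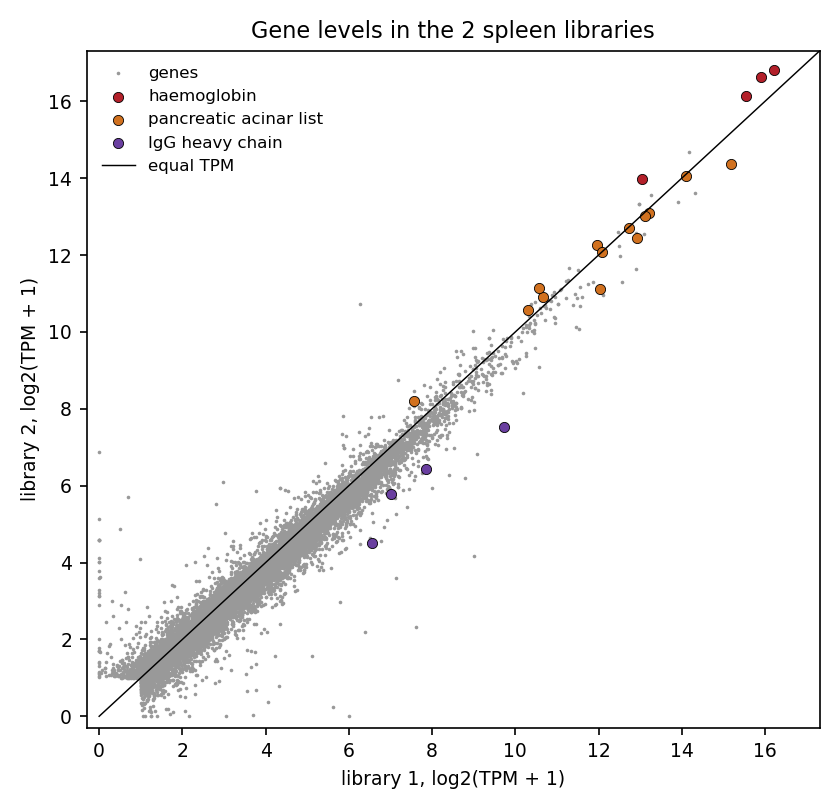
Each grey point is a gene with 1 TPM or more in at least 1 library, placed by its log2(TPM + 1) in library 1 (horizontal axis) and library 2 (vertical axis), with the line of equal TPM. The 4 haemoglobin genes lie above the line at the upper end, the 4 IgG heavy chain genes lie below it, and Pearson's r across the 13221 genes was 0.977.

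Markers of 20 of the 21 resident cell types had a median of at least 1 TPM in both libraries. B cells gave the strongest signal among lymphocytes, with all 10 genes of the B cell list detected and a list median of 122 ± 5.31 TPM. Cd79a and Cd79b, which encode the signalling chains of the B cell receptor, stood at 997 ± 189 and 515 ± 21.4 TPM and the inhibitory receptor gene Cd22 at 273 ± 38.2 TPM. The marginal zone B cell list had a median of 41.5 ± 0.0354 TPM, with the Notch target Dtx1 at 259.6 ± 75.7 TPM, Cd9 at 61.5 ± 0.375 TPM and the complement receptor gene Cr2 at 46.2 ± 6.71 TPM. Germinal centre genes were near the threshold. That list had a median of 1.34 ± 0.247 TPM, with Bcl6 at 24.1 ± 3.32 TPM and 4 of its 6 genes detected. Plasma cell genes had a median of 30.5 ± 6.08 TPM, and Jchain, the chain that joins IgM and IgA units, stood at 367 ± 30.4 TPM. Mzb1, Xbp1 and Derl3 of that list serve the secretory pathway, and Xbp1 and Derl3 are also used by pancreatic acinar cells.

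T cell genes lay lower, with a list median of 39.8 ± 2.86 TPM and all 10 genes detected. The T cell receptor constant region Trbc2 stood at 132 ± 6.41 TPM, the kinase gene Lck at 101 ± 5.20 TPM, Thy1 at 95.1 ± 3.44 TPM and Trac at 49.4 ± 1.39 TPM. Regulatory T cell genes had a median of 3.54 ± 0.258 TPM, with their transcription factor Foxp3 at 4.83 ± 0.721 TPM, and NK cell genes a median of 4.92 ± 0.587 TPM, with the granule gene Nkg7 at 87.1 ± 3.13 TPM and Prf1, which encodes perforin, at 14.6 ± 1.38 TPM. Within each library the B cell gene Cd79a exceeded the T cell gene Cd3e, 30.7-fold in library 1 and 22.4-fold in library 2. Cd4 exceeded Cd8a by 1.89-fold and 1.56-fold.

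Among myeloid cells, tissue macrophages were represented by their complement genes. C1qc stood at 403 ± 14.8 TPM, C1qb at 264.5 ± 13.2 TPM and C1qa at 198.5 ± 8.11 TPM, beside the haem-degrading enzyme Hmox1 at 308 ± 118 TPM, and all 12 genes of the red pulp macrophage list were detected with a median of 46.5 ± 9.78 TPM. The marginal zone macrophage list had a median of 22.6 ± 12.9 TPM. Monocyte genes had a median of 29.8 ± 5.50 TPM, with Ly6c2 at 193 ± 35.6 TPM and the growth factor receptor gene Csf1r at 125 ± 0.651 TPM. Neutrophil and granulocyte precursor genes had a median of 36.2 ± 5.28 TPM, with Camp, which encodes a granule peptide, at 99.8 ± 40.2 TPM. S100a8 was below S100a9 in both libraries, at 0.818-fold and 0.711-fold in TPM, or log2 ratios of -0.29 and -0.49. From expected counts, which are not corrected for length, the log2 ratios were -1.04 and -1.19. Conventional dendritic cell genes had a median of 6.59 ± 0.311 TPM and plasmacytoid dendritic cell genes a median of 43.2 ± 1.58 TPM. The latter list contains Klk1 (872 ± 47.6 TPM), which pancreas also expresses, and Ly6d (1220.1 ± 238 TPM), which B cells also express. Siglech, its more selective member, stood at 43.2 ± 1.58 TPM. Megakaryocyte and platelet genes had a median of 59.5 ± 5.79 TPM, led by the platelet chemokine Ppbp at 291 ± 17.9 TPM. Haematopoietic progenitor genes had a median of 5.06 ± 0.0495 TPM, with Kit at 10.3 ± 0.643 TPM. The mast cell and basophil list was the exception, at a median of 0.20 ± 0.0990 TPM with 1 of 5 genes detected.

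**Figure D2:**
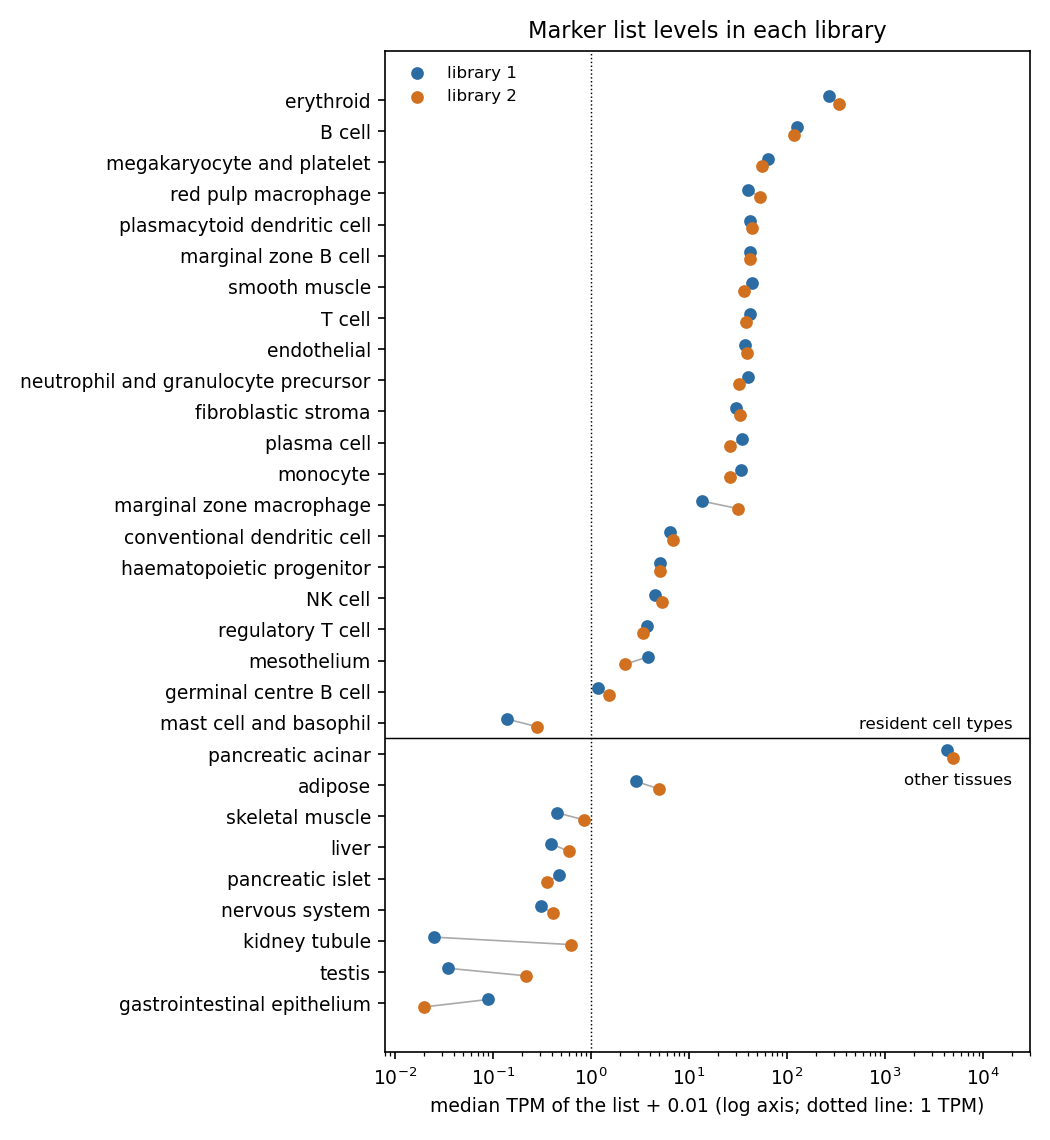
Each row is a marker list, with its median TPM in library 1 (blue) and library 2 (orange) on a log axis, after adding 0.01; resident cell types are above the horizontal line and other tissues below it. The dotted line marks 1 TPM, which 20 of 21 resident lists and 2 of 9 other tissue lists reached in both libraries, the pancreatic acinar list at 4605 ± 400.1 TPM.

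The framework of the organ was represented by endothelial genes (median 38.1 ± 0.965 TPM), fibroblastic stroma (31.7 ± 2.33 TPM), smooth muscle (40.4 ± 5.73 TPM) and mesothelium (3.01 ± 1.13 TPM). Plvap, a protein of fenestrated vessels, stood at 433 ± 77.6 TPM, and Stab2, a scavenger receptor of sinus endothelium, at 58.5 ± 8.63 TPM. The chemokines Ccl19 and Ccl21a, which guide lymphocytes into the white pulp, stood at 443 ± 29.2 and 279 ± 37.8 TPM. The actin gene Acta2 of contractile cells stood at 176 ± 19.4 TPM. All 5 transcription factors that pattern the embryonic spleen were detected in the adult organ, with a list median of 21.3 ± 7.71 TPM. Tlx1, without which no spleen forms, stood at 39.8 ± 8.80 TPM, Nkx2-5 at 23.4 ± 8.70 TPM and Wt1 at 21.3 ± 7.71 TPM.

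Of the remaining programmes, MHC class II genes had the highest median, 451 ± 75.6 TPM, and H2-Ab1 exceeded H2-Eb1 by 5.05-fold in library 1 and 3.66-fold in library 2. Proliferation genes had a median of 13.1 ± 2.28 TPM, with the replication clamp Pcna at 91.4 ± 25.2 TPM. Interferon-stimulated genes had a median of 7.96 ± 0.445 TPM. Immediate early genes had a median of 22.6 ± 2.81 TPM, with Junb at 108 ± 41.1 TPM. Heat shock genes had a median of 10.3 ± 0.417 TPM. The constitutive chaperone Hspa8 of that list reached 1511 ± 258 TPM.

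Transcripts of other tissues were low except for those of the exocrine pancreas and of fat. All 13 pancreatic acinar genes were detected in both libraries, at a list median of 4605 ± 400.1 TPM, and together took 10.5% of TPM in library 1 and 8.47% in library 2. The trypsinogen gene Prss2 stood at 8573 ± 370.4 TPM. Trypsinogen genes are near-identical copies and their division is uncertain. In the pancreatic islet list, the insulin genes Ins2 (20.4 ± 8.72 TPM) and Ins1 (4.54 ± 1.63 TPM) were detected, and the list median was 0.405 ± 0.0778 TPM. Adipose genes had a median of 3.91 ± 1.45 TPM, with Cfd, also called adipsin, at 68.3 ± 37.3 TPM and Adipoq at 3.96 ± 1.83 TPM. Medians of the other lists lay below 1 TPM: skeletal muscle at 0.64 ± 0.290, liver at 0.48 ± 0.141, nervous system at 0.35 ± 0.0707, kidney tubule at 0.318 ± 0.428, testis at 0.115 ± 0.127 and gastrointestinal epithelium at 0.045 ± 0.0495 TPM. Mitochondrial mRNA took 0.623% of TPM in library 1 and 0.659% in library 2, at a list median of 209.6 ± 7.41 TPM. The 4 Y-linked genes of the last list were each detected in both libraries, with Kdm5d at 5.79 ± 0.156 TPM and Eif2s3y at 4.69 ± 0.799 TPM, and the list median was 1.74 ± 0.332 TPM. Xist, the X inactivation transcript, had 5 counts in library 1 and 8 in library 2, 0.01 TPM in each.

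Between the libraries, 15 of the 38 lists were shifted. Lists of genes drawn independently would place 1.9 outside the percentiles. Genes of a marker list can vary together, so 1.9 is no chance expectation for the lists used here. The largest shifts among resident cell types were toward library 2, in the marginal zone macrophage, erythroid, NK cell and red pulp macrophage lists. All 12 red pulp macrophage genes were higher there, 11 of them beyond counting error by the exact binomial test, with a median log2 ratio of 0.62 (percentile 100 of the random lists). Cd5l differed by 1.17 and Hmox1 by 0.98 on the log2 scale, whereas C1qb, at 0.041, did not pass. The marginal zone macrophage list was higher by a median of 1.36 (percentile 99.995), with the receptor genes Cd209b at 1.72, Marco at 1.36 and Siglec1 at 0.35. In the erythroid list 9 genes were higher, among them Alas2, the enzyme that starts haem synthesis in red cells, at 1.16 and Hbb-bt at 1.10, and 2 were lower, Klf1 at -0.46 and Gata1 at -0.20, both transcription factors of red cell precursors. Its median was 0.77 (percentile 100) and its level 307 ± 50.4 TPM. NK cell genes had a median of 0.67 (percentile 99.99), with 5 higher and 1 lower beyond counting error. Klrb1c, which encodes the NK1.1 antigen, was at 1.32 and the transcription factor Eomes at -0.53.

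Smaller shifts toward library 2 were seen in the B cell list (0.10, percentile 98.6, 6 genes higher and 4 lower), the endothelial list (0.20, percentile 99.6, 6 higher and 2 lower), the fibroblastic stroma list (0.23, percentile 99.7, 6 higher and 1 lower) and the heat shock list (0.57, percentile 99.99, 4 higher and 1 lower), all counts being of genes beyond counting error. The mitochondrial list had a median of 0.44 with 11 genes higher and 1 lower, and this median was 0.097, percentile 88.3, once the trend of ratios with GC content and length was removed. Of the other tissues, kidney tubule genes were higher in library 2 by a median of 2.63, or 2.25 with genes at 0 counts set to the floor of 3 counts. Umod had 3 and 66 counts in libraries 1 and 2 (21.8-fold, counting interval 7.13 to 108) and Slc34a1 stood at 0.34 and 1.47 TPM. Adipose genes were higher by 0.93 with 5 of 6 beyond counting error. The acinar list was higher by 0.16 with 10 genes higher and 3 lower, but its median was -0.040 as a log2(TPM + 1) difference. Its genes together held less of the gene counts in library 2, 6.21% against 6.82% in library 1. The testis list (1.41, or 0.99 at the floor, percentile 97.65) had no gene with the 10 counts in total that the binomial test needs. It lost its place under 3 alternatives and had no value where members needed 50 or more counts. The other 2 shifted lists went toward library 1. Mesothelium genes were lower by a median of -0.57 (percentile 0.17), with 4 of 5 beyond counting error and Upk3b at -0.72. Islet genes were lower by a median of -0.71 (percentile 1.035), of which Ins2 (-0.71) and Ins1 (-0.60) passed. The other 23 lists were not shifted, among them the T cell (0.061), plasma cell (-0.075), monocyte (0.12), proliferation (-0.065) and interferon-stimulated (0.017) lists. In 11 of these 23, by a rule chosen after the data were seen, genes beyond counting error in 1 direction outnumbered those in the other by 3 or more. Of these, 7 lists went toward library 1. All 5 genes were lower in library 2 in the spleen patterning list (-0.33, percentile 2.515, 3 beyond counting error) and in the smooth muscle list (-0.21, percentile 12.7, 4 beyond counting error). Beyond counting error, 6 immediate early, 4 proliferation and 3 regulatory T cell genes were lower and none higher, and 4 plasma cell genes were lower against 1 higher and 6 MHC class II genes against 3. The other 4 went toward library 2, with 5 T cell genes higher against 1 lower, 4 conventional dendritic cell genes against 1, and 3 against none in both the skeletal muscle list (0.71, percentile 97.4) and the list of Xist and Y-linked genes (0.44, percentile 97.2). The liver list was not shifted either, with 1 gene higher in library 2 and 1 lower beyond counting error. In that list Serpina1a, 1 of several near-identical copies, stood at 10.7 TPM in library 1 and 0.58 TPM in library 2.

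**Figure D3:**
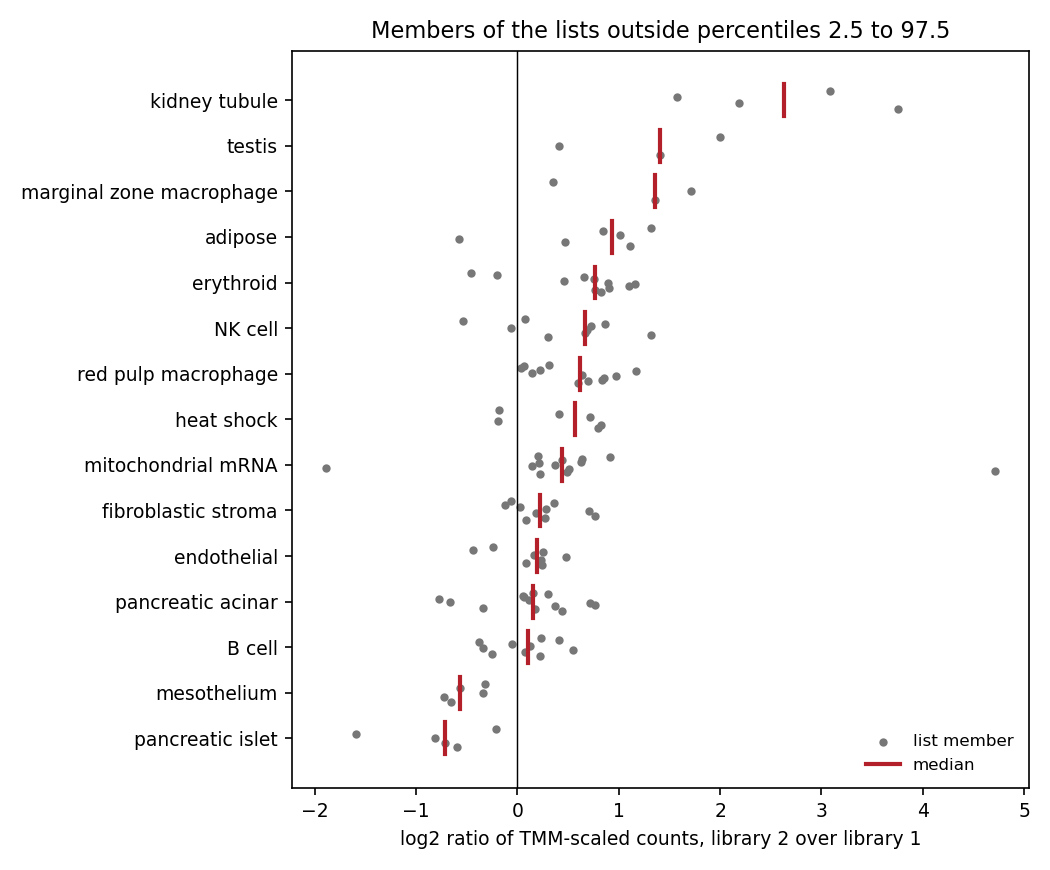
Each point is a member of 1 of the 15 shifted lists, placed by its log2 ratio of TMM-scaled counts (library 2 over library 1), and the red bar is the list's median. The medians run from -0.71 for the pancreatic islet list to 2.63 for the kidney tubule list, and all 12 red pulp macrophage genes lie above 0.

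Immunoglobulin transcripts differed between the libraries by class. IgM, the first class a B cell makes, was the most abundant heavy chain, with Ighm (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730, minus strand) at 5292 ± 621 TPM, and it exceeded Ighd by 16.3-fold in library 1 and 14.2-fold in library 2. All 4 IgG genes were lower in library 2 and passed the exact binomial test. Ighg2c stood at 849 TPM in library 1 and 184 TPM in library 2 (log2 ratio -2.06), Ighg1 at 93.3 and 21.9 TPM (-1.91), Ighg2b at 229 and 85.0 TPM (-1.28), and Ighg3 at 128 and 53.8 TPM (-1.10). Igha moved the other way, at 526 and 764 TPM (0.68), and Ighm had a log2 ratio of -0.098. Accordingly the ratio of IgM to IgG transcripts was 4.41 in library 1 and 14.1 in library 2, and that of IgM to IgA 10.9 and 6.35. Light chains were mostly kappa. Igkc, at 13009.9 ± 3313 TPM, exceeded the lambda gene Iglc2 by 35.02-fold and 30.3-fold in TPM, log2 ratios of 5.13 and 4.92, but from expected counts, not corrected for length, the log2 ratios were 3.29 and 3.22. The lambda genes Iglc1 and Iglc3 had no matched identifier and are not in that ratio, and the ratio of alpha to delta T cell receptor constant regions was not computed because Trdc had no matched identifier. Hbb-bs exceeded Hbb-bt by 7.28-fold and 6.26-fold.

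**Figure D4:**
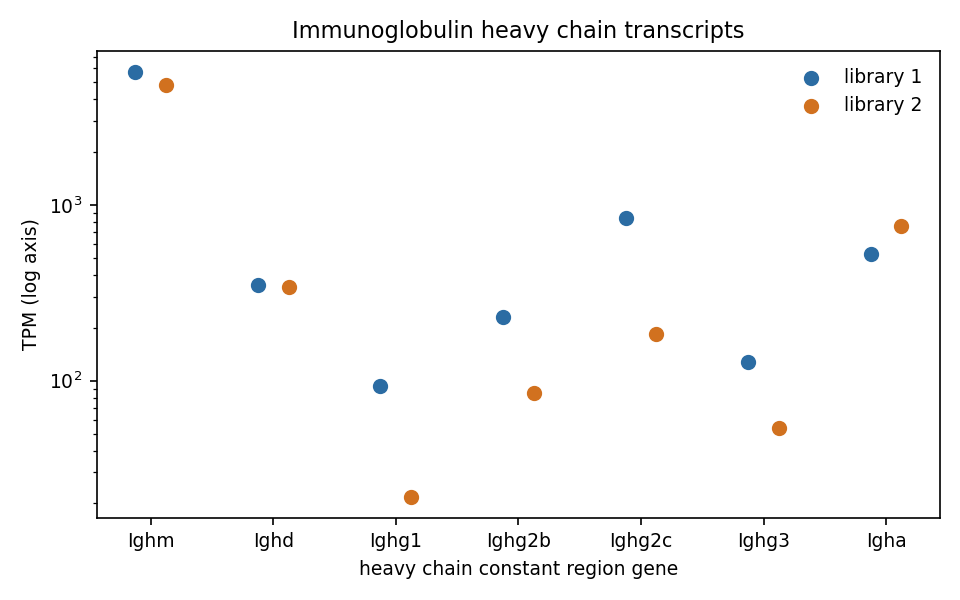
TPM of each heavy chain constant region gene on a log axis, in library 1 (blue) and library 2 (orange). The 4 IgG genes are lower in library 2, from 849 to 184 TPM for Ighg2c, while Igha is higher, from 526 to 764 TPM.

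The largest ratios between the libraries fell mostly on pseudogenes. Of the 20 genes named, 11 are annotated as pseudogenes, 8 of the 10 that were higher in library 1 and 3 of the 10 that were higher in library 2. Their reads can be shared with parent genes, and all 11 had counts that were not whole in at least 1 library. Toward library 1 these were Gm8730 (27.3-fold), Gm9625 (44.5-fold), Gm14165 (225-fold), Gm6472 (20.5-fold), Gm8226 (48.8-fold), Gm7278 (26.4-fold), Gm10925 (at least 474-fold) and Rplp0-ps1 (at least 84.1-fold). Toward library 2 they were Rpl7a-ps11 (at least 118-fold), Gm10182 (at least 35.5-fold) and Gm6969 (84.3-fold, counting interval 23.95 to 347). The enolase copy Eno1b (45.3 and 4199 counts, 91.7-fold) is uncertain for the same reason. Outside the pseudogenes, Dct (ENSMUSG00000022129, chromosome 14, 118012790 to 118052244, minus strand), an enzyme of melanin synthesis, had 0 counts in library 1 and 960 in library 2, at least 317-fold higher against a floor of 3 counts. Tyrp1, another enzyme of that pathway, had 1 and 252 counts, a 249-fold ratio with a counting interval of 44.4 to 9892. The antisense gene BC018473 had 0 and 1676 counts, at least 553-fold higher, Gm20431 had 0 and 1281 counts, at least 423-fold higher, and Trpc2 had 0 and 152 counts, at least 50.1-fold higher. The antisense gene Gm27177 had 2.5 and 191 counts, a 75.8-fold ratio with a counting interval of 25.8 to 786. Toward library 1, the kallikrein gene Klk1b22 had 370 counts against 1, a 374-fold ratio with a counting interval of 66.7 to 14802, and the cell adhesion gene Cntn2 had 129 against 2, a 65.2-fold ratio with an interval of 17.7 to 544. Gm20431, Gm27177 and Trpc2 had counts that were not whole, so some of their reads were divided with other genes.

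The transcript that led a gene was mostly the same in both libraries. Among 4665 genes with at least 2 annotated transcripts, 88.2% had the same leading transcript, and 41.8% had a second transcript at 20% or more of the gene's TPM in both libraries, or 68.0% with a share of 10%. Ighm-201 (ENSMUST00000103426) held 74.1% ± 2.67 of Ighm TPM and Ighm-202 held 25.9% ± 2.67. Ighd-202 held 99.3% ± 0.184 of Ighd. Pkm-201, 1 of 2 Pkm transcripts listed, held 95.1% ± 0.601, and Cd74-201 held 87.4% ± 0.792. Cd44-203 held 66.4% ± 6.44 of the adhesion receptor Cd44 and Ikzf1-201 held 62.8% ± 4.19 of the lymphoid transcription factor Ikzf1. For Ptprc, which encodes the leukocyte antigen CD45, Ptprc-213 held 39.1% ± 3.69 and Ptprc-207 held 34.2% ± 0.00707 of TPM. The first of these is only 702 nucleotides long, against 5074 for the second, so its TPM rests on short sequence that longer transcripts can share.

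The pooled lists of the authors, on the mm9 assembly, described 428708 splice junctions with 47250741 junction reads and 687468 contigs that covered 254159402 bases. Junctions had a median of 2 reads and 41.9% had a single read. Contigs had a median length of 244 nucleotides. Of all junctions, 77.0% (exact 95% interval 76.9 to 77.2%) had both ends in contigs of the same strand. Among entries with 0.01 or less in the column taken as the irreproducibility value, which has no name in the files, 111845 junctions remained and held 98.4% of the reads, and 93.0% of them had both ends in such contigs. The junction with the most reads, on the plus strand of chromosome 11 from 32184129 to 32184262, held 2667199 reads, 5.64% of the total. The next highest lay on the same strand, shared ends with it or each other, and held nearly as many. They ran from 32184129 to 32197079 (2578327 reads) and from 32196946 to 32197079 (2577583 reads). Whether reads that match several places were counted at more than a single junction was not tested. The total and the shares of it may therefore not count distinct reads. The contig of highest level lay on the plus strand of chromosome 16, from 11143987 to 11144423. These lists pool the libraries, so they carry no SD.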

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

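Reads of the added spike-in RNA lie outside every comparison of the report and were well above the limit that a count of 0 allows. They came to 335223 in library 1 and 646217 in library 2, which is 0.670% and 1.24% of all expected counts. Of the 97 spike-ins listed, 68 were detected in library 1 and 71 in library 2. The 37 spike-ins with at least 50 counts in each library had a median log2 ratio of 0.88 for library 2 over library 1 against the TMM-scaled gene counts, with a range from -0.014 to 1.32. The amount added to each library is not given in the sources used here, so no explanation is weighed. No outlier could be tested for in a group of 2, and with a single group no difference between groups exists.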

How the results depend on the processing

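Most summary values kept their size under the alternatives, and 2 libraries bound the precision of all of them. The number of genes detected in both ran from 8392 at 5 TPM to 16454 at 0.1 TPM, within 1.5 times of the main count. Pearson's r across genes was 0.964 with a pseudocount of 0.1, 0.992 with no filter, 0.963 on posterior mean TPM and 0.984 on TMM-scaled counts. The biological coefficient of variation was 0.212 with no filter, 0.164 with a filter of 100 counts, 0.176 from the trended dispersion at the median gene and 0.0832 from the median of DESeq2's gene-wise dispersions. The share of genes within 2-fold was 98.6% above 10 TPM and 96.9% as a TPM ratio. The count of genes beyond counting error was 8795 under total count scaling and 8811 under DESeq2 size factors, of which 41.8% and 46.7% were higher in library 2 against 48.3%. It fell to 977 when a fold of 2 was also required, 62.8% of them higher in library 2, an alternative added after the data were seen. Genes with the same leading transcript came to 86.9% from a gene TPM of 1. Genes with a second transcript in use came to 68.0% at a share of 10%, and to 48.3% and 49.8% in single libraries, where agreement of both is not required. Junctions with both ends in contigs came to 93.0% at an irreproducibility value of 0.01 or less, 66.2% when the contig had to cross each splice site and 80.4% when strand was ignored. Filters, thresholds and single libraries change the genes or entries counted. For the other alternatives the cause was not tested.

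The number of shifted lists was 14 or 15 under each of the 6 alternatives, and between 13 and 14 of the 15 lists were the same. The acinar median turned to -0.040 as a log2(TPM + 1) difference, still at percentile 98.7, on a scale where the median detected gene stood at -0.15 as a log2 TPM ratio. The testis list lost its place under total count scaling, DESeq2 size factors and removal of the trend with GC content and length, and the mitochondrial list under the last. Where members needed 50 or more counts, the testis list had no value. The skeletal muscle list gained a place under 2 alternatives, and the spleen patterning and proliferation lists under 1 each. The trend with GC content and length, removed after the data were seen, took 6.31% of the variance of log ratios and had a value for 99.3% of list members. The number of resident lists at 1 TPM or more stayed 20 in every alternative that kept both libraries, and the number of ratios above 1 stayed 8 of 9 on posterior mean TPM and expected counts. Of 408 ratios of named genes under total count or DESeq2 scaling, 397 kept their side of the threshold, 7 came to pass it, 4 no longer passed it and none turned. A library alone always lies within the SD of 2, and ratios within a library are alike in FPKM and TPM, so neither is counted here. Of 150 list levels 98 stayed within the SD of the libraries, and 31 of the 52 that moved did so when immunoglobulin, haemoglobin and mitochondrial genes were left out of TPM. Of 18 ratio values 13 stayed. The other 5 were all from expected counts, which are not corrected for length, with mean log2 ratios of 3.26 for kappa over lambda, 3.68 for IgM over IgD, 3.63 for IgM over IgA, 2.59 for Hbb-bs over Hbb-bt and -1.11 for S100a8 over S100a9, against 5.03, 3.93, 3.06, 2.76 and -0.39 in TPM. Results that need both libraries have no value with a library left out. No paired analysis was possible because there is only 1 group.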

Other observations

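Of what follows, the melanocyte, eosinophil and chymotrypsin genes were chosen after the ratios had been seen, and so were the tests on acinar genes and on the level of Xist. The tests on Tsix, on long nuclear transcripts, on skin and eye genes and on the second melanocyte set were fixed before their values were seen.

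Several genes of pigment cells were higher in library 2. Their list was written after the values had been seen, so the counts that follow describe this pattern and do not test it. Of 12 melanocyte genes, 11 had at least 10 counts in total, all 11 were higher in library 2, and 10 of them passed the exact binomial test. Dct had 0 and 960 counts and Pmel, which forms the fibrils of the pigment granule, 50 and 857 counts in libraries 1 and 2, a 16.97-fold ratio with a counting interval of 12.8 to 23.0. Mlana had 1 and 29 counts (28.7-fold, interval 4.76 to 1173), Tyr, the first enzyme of melanin synthesis, 0 and 15 counts, and Oca2 0 and 14 counts. The lineage transcription factor gene Sox10 was 3.01-fold and Gpnmb 3.29-fold higher, while Mitf, which macrophages also express, did not pass (256 and 276 counts). The red pulp and marginal zone macrophage lists were higher in library 2 as well, by median log2 ratios of 0.62 and 1.36. Whether macrophages account for the rise of Gpnmb was not tested. The gene of highest level, Dct, reached 8.82 TPM in library 2.

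Library 1 held more of several eosinophil granule transcripts, beside its higher IgG transcripts. Epx, the eosinophil peroxidase gene, had 1088 and 292 counts in libraries 1 and 2, a 3.76-fold ratio. Prg2, which encodes the major basic protein, was 2.63-fold higher in library 1, Ear1 2.49-fold and Ear6 3.59-fold. The family did not move as a whole. Of 10 eosinophil genes, 5 were higher in library 1 and 2 higher in library 2 beyond counting error, with a median log2 ratio of -0.41, and the eotaxin receptor gene Ccr3 was 1.57-fold higher in library 2. Ear genes are near-identical copies and their division is uncertain.

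Ctrc, which encodes the pancreatic protease chymotrypsin C, departed from the rest of its tissue. It stood at 76.3 TPM in library 1 and 1698 TPM in library 2, a 26.2-fold ratio with a counting interval of 25.2 to 27.3, while the 13 genes of the acinar list differed by a median of 1.12-fold. Most of it was assigned to Ctrc-204 (chromosome 4, 141838239 to 141846357 of GRCm38), a transcript annotated without a coding sequence, which held 72.6% and 99.5% of the gene's TPM. Ctrc is known to carry a natural deletion in C57BL/6 mice that disables it. Whether the animals of the libraries differed at this gene was not tested, since that needs the reads. Sycn and Prss3 went the other way, with log2 ratios of -1.07 and -2.46, and Prss3 is 1 of several near-identical trypsinogen genes.

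The first pattern weighed is the level of pancreatic acinar transcripts, a list median of 4605 TPM in a spleen library. Sharing of reads between near-identical paralogs is argued against for the 6 acinar genes without such a copy, whose lowest mean was 241 TPM. The limit of 10 TPM for these genes was set after values had been seen, so it is no independent test. A candidate explanation is pancreatic RNA mixed with the spleen RNA, since the tail of the pancreas touches the spleen. It stays open here, because the second set of 18 acinar genes, of which 83.3% reached 10 TPM in both libraries, was written after values had been seen and holds Sycn, already among the highest, so it adds no independent support. Islet tissue may have been included, as the lowest value of Ins1 and Ins2 was 3.38 TPM, but this rests on those genes and the list median was below 1 TPM. Pancreatic tissue in the dissected sample, mixed RNA and mixed library molecules would give these values alike, and the design names no biological contrast, so no biological explanation was tested.

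The second pattern is Xist at 5 and 8 counts beside 4 detected Y-linked genes, in tissue that the labels assign to littermates of both sexes. RNA of females in a share like that of males is argued against by the upper 95% Poisson limit of Xist, which was at most 0.273 TPM even at the length of its shortest transcript, against 5.79 TPM for Kdm5d. Assignment of Xist reads to its antisense partner Tsix is argued against by Tsix at 0 TPM in both libraries. A complete loss of long nuclear transcripts is argued against by Malat1 and Neat1, the 2 of 3 such transcripts that reached 1 TPM in both libraries. They stood at 119 and 167 TPM on average. The third, Kcnq1ot1, stood at 0.20 TPM in library 1 and 0.32 TPM in library 2. A partial loss stays open, since abundant transcripts could pass 1 TPM in spite of it. What also stays open is whether only males, or almost only males, gave RNA to these libraries, which all of these values allow.

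The third pattern is the pigment cell transcripts of library 2. Skin carried into the sample is argued against by epidermal genes, whose highest value in library 2 was 0.98 TPM against 8.82 TPM for Dct. Eye tissue is argued against by eye genes, whose highest value there was 0.48 TPM. Melanocytes within the spleen tissue, which are known in pigmented mice, stay open as a hypothesis. A second set of 8 melanocyte genes had a median log2 ratio of 0.33 over the 6 with at least 10 counts, 5 of them higher in library 2, short of the median of 1 that was set for it and above the 0 that would have argued against it. Several of those genes were at similar levels in library 1, where other cells express them.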
